A study of Mus musculus with 4 samples.

How the data were processed

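Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and inserts sequencing adapters, in mouse embryonic stem cells of the line 2TS22C. Per the labels, the endogenous Sox2 gene was silenced, the cells were treated with DOX, and a lentivirus supplied either SOX2 or SOX17FNV, an engineered form of SOX17. Each group had 2 libraries, which the titles call biological replicates, and each library started from 900000 cells. The labels do not say whether the replicates came from separately derived lines, so the spread between them is the spread between these libraries.

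The authors deposited 1 peak list per library, and the peak names in each list carry a single library, so peaks were called per library and not on pooled reads. The tools named in the submitters' processing notes are Bowtie2, SAMtools and MACS2, and the build named there is mm10. Their versions, settings and filters, and any shift of the reads for the transposase, are not given in the sources used here. Each deposited line holds a fold enrichment, the ratio of the summit's pileup to the local background, as the peak caller wrote it. The deposited lines also hold the -log10 of the p-value and of the q-value of the summit. The lowest -log10 q in every list was 1.30, which corresponds to a q of 0.05. The deposited score was 10 times the -log10 q rounded down in 99.9869% to 99.9986% of the lines of a list. These values are the authors' own per peak and were used only to describe, rank or filter peaks within a list. Positions are given in mm10, counted from 1.

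A peak was taken as a distinct interval, since an interval with several summits fills several lines of the list. The files give no read totals, so depth was read from the peak values. MACS2 writes the fold as (pileup + 1)/(background + 1) together with a Poisson p, and both were solved for the pileup. A whole-number pileup gave the deposited -log10 p within a tolerance of 0.001 for 100% of the summits of every list, with a largest difference of 0.00014. The lowest background in a list stands for the genome-wide background pileup, which grows with depth. On simulated summits, the step recovered all of 50000 pileups.

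The peaks of the 4 lists on chromosomes 1 to 19, X and Y were pooled, and peaks that overlapped by at least 1 bp were merged into 170898 regions. A library called a region when at least 1 of its peaks lay in it. SOX17FNV-only regions were called in both SOX17FNV libraries and in neither SOX2 library, and SOX2-only regions the reverse. The same counts were made for the other 2 ways of splitting the 4 libraries into pairs, by replicate number and crossed. With 2 libraries against 2 there are 3 splits, and no exact permutation test can give a p below 0.333. Overlap of lists was measured as the Jaccard index, the shared base pairs over all covered base pairs. The step that counts regions was run on 79607 simulated regions, and it returned the simulated totals of SOX17FNV-only, SOX2-only and shared regions. These regions were spaced apart and the peaks of each overlapped by construction. The run therefore checks the code and not how close neighbours merge.

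Gene spans and symbols came from the reference gene table for GRCm38.p6, whose chromosome coordinates are those of mm10. That table holds gene spans without strand, transcription start sites or exons, and no genome sequence was used here. The planned shares of promoter, exonic, intronic and intergenic regions were therefore replaced. A region was counted as near a gene end when it lay within 1 kb of either end of a protein-coding gene span, and otherwise as inside a gene, outside but within 50 kb, or farther away. The planned nearest transcription start site was replaced by the nearest of 21887 protein-coding gene spans within 50 kb, with ties settled by the nearest gene end. In this way 147339 regions (86.2%) were assigned to a gene. The planned motif counts were not run.

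Shares are given with exact binomial 95% intervals, which cover counting error only. Region lists were compared with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. The 95% intervals of odds ratios are normal approximations on the log scale. Where a count in a comparison was 0, a small constant was added to each of its counts. The log2 odds and interval then depend on that constant. These tests run over regions and compare the region lists of these libraries, not the conditions, because regions are not replicates. For 12 gene lists (142 genes, all found in the table), the SOX17FNV-only share of the group-specific regions assigned to a list was tested against the same share for all other genes. The SOX17FNV-only count minus the SOX2-only count of each list was also placed among 10000 random gene lists of the same size, matched on the number of regions per gene. In simulations on the 18599 genes with a region, the test called 0% of lists with a true odds ratio of 1, 12% with an odds ratio of 4 and 26% with an odds ratio of 16, over 50 simulations each.

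The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took 3 sets. The first was, for each direction, the 10 regions whose lower percentile by -log10 p within the 2 lists that call them was highest. The second was, for each direction, the 5 genes with the most group-specific regions in that direction and none in the other, with ties going to the gene with more regions in all 4 libraries. The third was up to 4 genes of each list with the most group-specific regions, and Sox2 and Sox17 in every case. The results of some genes are not reported here. Alternatives covered stricter q thresholds, lists of equal length (92851 peaks, the length of the shortest list), the strongest 50000 peaks of each list, 50% coverage of a region, windows of 250 bp around summits, other gene assignments, a replicate block and leaving out each library. Leaving out chromosome 14, and chromosomes 6, 14 and X, was added after seeing the data, as was every alternative for the chromosomes other than lists of equal length. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, BEDTools 2.31.1 and Matplotlib 3.10.9.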

Results

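Accessible chromatin was mapped in 2TS22C mouse embryonic stem cells. Per the labels, their endogenous Sox2 gene was silenced, they were treated with DOX, and a lentivirus supplied their SOX factor. One group carried SOX2, a transcription factor needed for pluripotency. The other carried SOX17FNV, an engineered form of SOX17, a related factor of endoderm. The cells grew in 2i serum/LIF medium, which holds stem cells in a naive state. The comparison asks where the accessible chromatin of cells kept by the engineered factor differs from that of cells kept by SOX2. There were 2 libraries per group, and peak lists in place of read counts.

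The SOX17FNV libraries held 120341 and 92851 peaks, and the SOX2 libraries 123214 and 96500 peaks. The group means were 106596 ± 19438 and 109857 ± 18890 peaks (SD, n = 2), so the groups differed by less than the replicates within each. Replicate 1 of either group had the longer list and the wider peaks, with median widths of 441 and 445 bp against 384 and 378 bp in replicate 2. The genome-wide background pileup, which grows with depth, was 3.91 and 3.27 in the SOX17FNV libraries and 4.17 and 5.02 in the SOX2 libraries. The weakest summits in the lists had pileups of 11, 10, 12 and 13 in the same order. Divided by the width of the narrowest peak of each list, the background was 23.3, 22.4, 25.3 and 37.4 per kb, again in this order. SOX2 replicate 2, with the highest background, had the lowest median fold enrichment, 2.99 against 3.43 to 3.52 in the other libraries.

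At Sox2 (chromosome 3, 34649995 to 34652461), a region at 34648572 to 34650207 that reaches into the gene span was called in all 4 libraries. Its highest summit pileups were 58 and 40 in the SOX17FNV libraries and 62 and 56 in the SOX2 libraries. A region within the gene at 34650574 to 34651198 was called in both SOX2 libraries, with pileups of 56 and 48, and in neither SOX17FNV library. A further SOX2-only region lay at 34691446 to 34691709, 38985 bp from the gene. At Sox17 (chromosome 1, 4490928 to 4497426), the region at 4491737 to 4493783 inside the gene was called in all 4 libraries. Its highest summit pileups were 84 and 88 in the SOX17FNV libraries against 61 and 49. Relative to the median pileup of regions called in all libraries, these were 3.11 ± 0.793 and 1.75 ± 0.00505 (SD, n = 2), and the groups did not overlap. The exact permutation p cannot go below 0.333 here. At the other end of Sox17, a region at 4496787 to 4497470 was SOX2-only. The labels do not give the sequence of the lentiviral genes, and reads from a mouse cDNA would map to the exons of these genes.

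**Figure D1:**
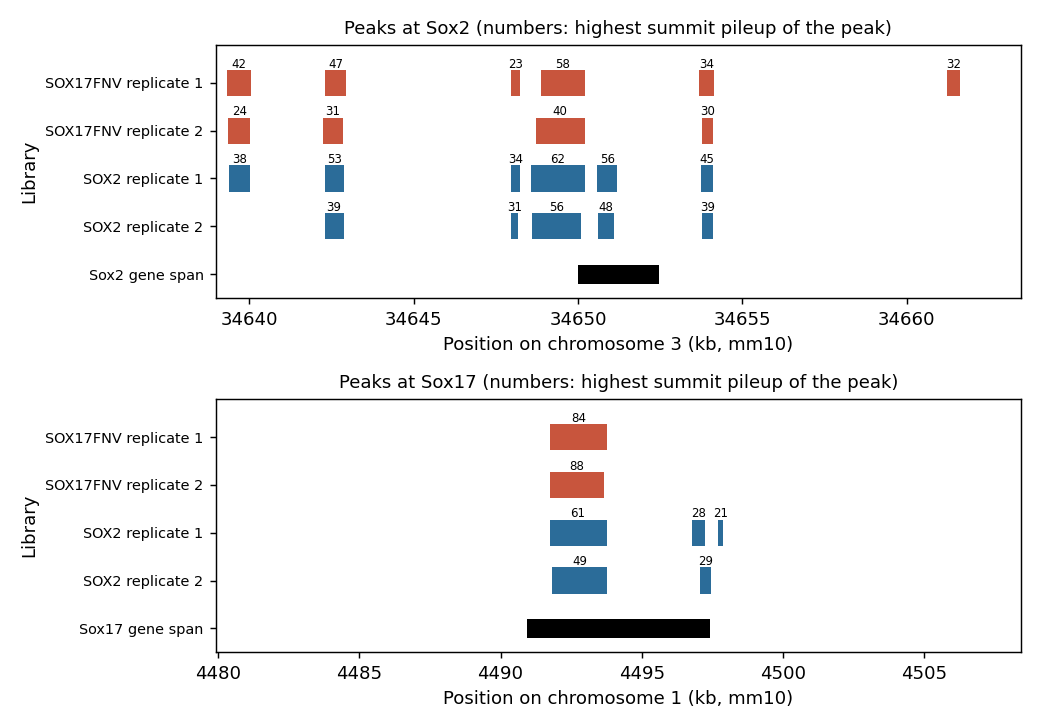
Peaks of the 4 libraries within 10 kb of Sox2 and Sox17, with position in kb (mm10) on the horizontal axis and a row per library above the gene span. Bars are deposited peaks and the number above each is its highest summit pileup; inside Sox2 the peak with pileups of 56 and 48 was present in the SOX2 libraries alone, and the Sox17 peak was highest in the SOX17FNV libraries.

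Regions called in all libraries were stronger than group-specific ones, which the calling rule itself favours. A shared region had to pass the threshold in all 4 lists, and a group-specific one to miss it in both lists of a group. Of 170898 regions, 57783 (33.8%) were called in all 4 libraries, 5228 (3.06%) were SOX17FNV-only and 6994 (4.09%) were SOX2-only. All 12 general pluripotency genes, Pou5f1, Nanog and Sall4 among them, had a called region within 1 kb of either gene end in each library. So did 10 or 11 of 11 primitive streak and mesoderm genes and 10 or 11 of 12 housekeeping genes. The share over all genes was not computed. The median percentile of group-specific regions within the lists that called them was 32.7 and 29.9 for SOX17FNV-only regions and 37.6 and 30.6 for SOX2-only regions, against 67.0 to 74.6 for shared regions.

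The number of regions that followed the factor, 12222, did not exceed the 12967 that followed the replicate number, while the crossed split gave 4648. The split by number was uneven. Of its regions, 11824 were called in the replicate 1 libraries alone, which had the longer lists, and 1143 in the replicate 2 libraries alone. The split by factor gave 5228 SOX17FNV-only and 6994 SOX2-only regions. With lists of equal length the split by factor gave 11706 regions, the split by number 7701 and the crossed split 4298. The Jaccard index was 0.515 for the SOX17FNV pair and 0.509 for the SOX2 pair, 0.553 and 0.5004 for libraries of the same number, and 0.478 and 0.469 for the remaining pairs. The mean within groups exceeded the mean between groups by 0.0123 (exact permutation p = 0.667, with 0.333 the smallest possible). This difference was -0.000421 when only peaks with -log10 q of at least 5 were used, and -0.0126 with at least 10. The counts rest on both libraries of a group. SOX17FNV-only regions numbered 14148 without SOX17FNV replicate 1, 25111 without SOX17FNV replicate 2 and 14910 without SOX2 replicate 1, and SOX2-only regions 16340 without SOX17FNV replicate 1, 18628 without SOX2 replicate 1 and 28780 without SOX2 replicate 2.

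**Figure D2:**
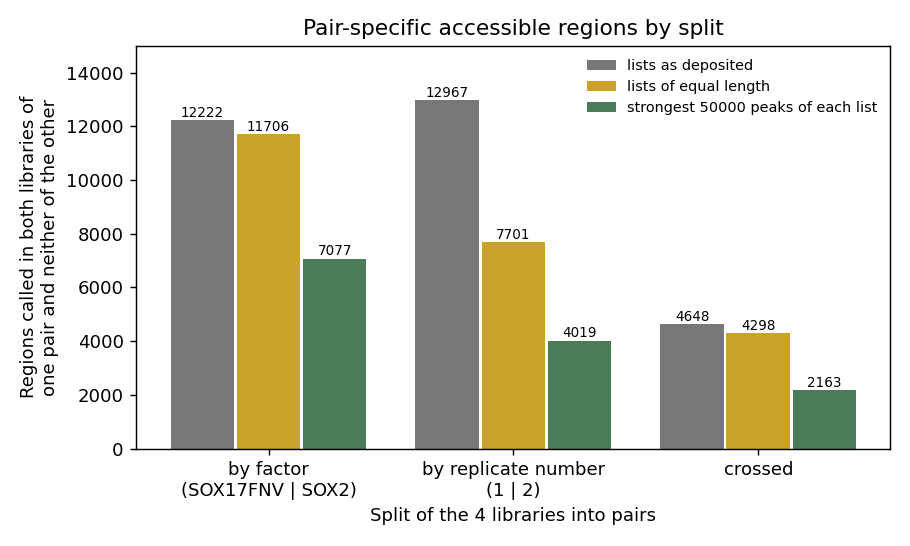
Number of regions called in both libraries of a pair and in neither library of the other pair (vertical axis), for the 3 splits of the 4 libraries (horizontal axis). Bars are summed over both directions; with lists as deposited the split by factor (12222) lies below the split by replicate number (12967), and with lists of equal length it lies above (11706 against 7701).

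The strongest SOX17FNV-only regions lay inside Sgcd, which encodes a sarcoglycan of muscle membranes (chromosome 11, 47495727 to 47496441), inside Ccser1 (chromosome 6, 61282727 to 61283248) and 20698 bp from Ric3, a chaperone of acetylcholine receptors (chromosome 7, 109104130 to 109104999). The Sgcd region had pileups of 35 and 31 and stood at the percentiles 89.0 and 90.5 of its lists. Further regions among the strongest 10 were assigned to Cnbd2, Nub1, Sec31a and Galnt10, and 3 had no protein-coding gene within 50 kb, on chromosomes 12, 4 and 17. The strongest SOX2-only region lay 7379 bp from Rbm25, a splicing factor gene (chromosome 12, 83624212 to 83624829), with fold enrichments of 8.05 and 7.53 at the percentiles 95.1 and 96.8. It was followed by a region 12696 bp from Itprid1 (chromosome 6, 55791161 to 55792594) and by regions inside Nrg1, which encodes neuregulin (chromosome 8, 32044198 to 32045190), Alk, a receptor tyrosine kinase gene (chromosome 17, 72556701 to 72557681), Myo6, which encodes an unconventional myosin (chromosome 9, 80283711 to 80285286), and Eya1, a developmental transcription cofactor gene (chromosome 1, 14225323 to 14226276). One lay 5248 bp from Pdk1, a kinase gene of glucose metabolism, and 3 had no gene within 50 kb, on chromosomes 6, 10 and 2.

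The genes with the most SOX17FNV-only regions and no SOX2-only region were Fhit with 16 of its 77 regions, Enox1 with 10 of 75, Hs6st3, a heparan sulfate sulfotransferase gene, with 10 of 46, Gpc5, which encodes a glypican, with 8 of 40, and Thrb, a thyroid hormone receptor gene, with 8 of 35. All 5 lie on chromosome 14, where regions shared by all libraries had pileups 1.29 times as high in the SOX17FNV libraries as in the SOX2 libraries, relative to other autosomes. The genes with the most SOX2-only regions and no SOX17FNV-only region were Cobl, an actin nucleator gene on chromosome 11, with 16 of 81, Sox5, a SOX factor gene on chromosome 6, with 9 of 76, Zswim6 on chromosome 13 with 7 of 33, Fam189a1 on chromosome 7 with 7 of 32, and Xiap, which encodes an inhibitor of apoptosis, on chromosome X with 7 of 26. Both rankings are by count and were not adjusted for the number of regions per gene. Sox5 lies in a part of chromosome 6, from 120 to 150 Mb, where the same pileup ratio was 0.844, and Xiap in a part of chromosome X, from 5 to 45 Mb, where it was 0.724. Cobl kept 1 SOX2-only region, beside 2 SOX17FNV-only ones, among the strongest 50000 peaks of each list. Leaving out 1 library moved these counts, since a region then needed a single library of that group. Without SOX17FNV replicate 1, SOX17FNV-only regions outnumbered SOX2-only regions by 34 at Fhit, 29 at Enox1, 23 at Hs6st3, 17 at Gpc5 and 17 at Thrb. Without SOX2 replicate 2 the difference was -33 at Cobl, -27 at Sox5, -14 at Fam189a1, -13 at Xiap and -12 at Zswim6, and without SOX17FNV replicate 2 it was -6 at Cobl. With -log10 q of at least 5 the differences shrank to 9 at Fhit, 7 at Enox1, 1 at Hs6st3, 6 at Gpc5 and 2 at Thrb, and to -1 at Cobl, -4 at Sox5, -2 at Zswim6, -1 at Fam189a1 and -1 at Xiap.

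None of the 12 gene lists had a SOX17FNV-only share that passed the adjusted threshold in Fisher's exact test. The smallest adjusted p was 0.281, and 1 list, germ line, had an unadjusted p below 0.05 (0.0365). Over 15 alternatives the sign of the log2 odds turned in 0 for germ line and primitive streak and 1 each for general, formative and endothelial genes. It turned in 2 each for naive and trophectoderm, 3 for endoderm, 4 for neuroectoderm and 6 for housekeeping genes. For fibroblast genes it turned in 4 of 14, and for two-cell-like genes in 1 of 12. Of the group-specific regions of the genes outside the germ line list, 4370 were SOX17FNV-only and 5628 SOX2-only, a SOX17FNV-only share of 43.7%. Without SOX17FNV replicate 2 there were 25111 SOX17FNV-only and 9022 SOX2-only regions in all, and without SOX2 replicate 2 there were 7470 and 28780. Differences at single genes then lean toward the group left with 1 library, and they were not set against these totals. Of 54 named genes, 10 changed direction in the first of these settings and 5 in the second. Without SOX17FNV replicate 1 or SOX2 replicate 1, 0 did.

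Among general pluripotency genes, all 5 group-specific regions were SOX2-only: 2 were assigned to Sox2, 2 to Nanog, a core pluripotency factor gene, and 1 to Dppa2. The Nanog regions lay 31881 and 3576 bp from the gene, in the part of chromosome 6 where the pileup ratio of shared regions was 0.844. Among naive pluripotency genes there were 4 SOX17FNV-only and 14 SOX2-only regions. Nr5a2, a nuclear receptor gene, had 2 and 4, Esrrb, an orphan nuclear receptor gene, 1 and 3, Tfcp2l1 none and 2, and Tbx3 none and 2. The log2 odds were -3.10 (95% interval -7.27 to 1.08) for the general list and -1.45 (-3.05 to 0.16) for the naive list, both with an adjusted p of 0.281 by Fisher's exact test. The value of the general list includes the added constant, since it had no SOX17FNV-only region. The differences in counts of these lists, SOX17FNV-only minus SOX2-only, stood at the percentiles 13.9 and 12.1 of the random lists. Formative and primed pluripotency genes had 6 SOX17FNV-only and 2 SOX2-only regions (log2 odds 1.95, -0.36 to 4.26, exact adjusted p = 0.281). Lef1, a transcription factor gene of the Wnt pathway, had 4 and 1, Dnmt3a, a DNA methyltransferase gene, and Pou3f1 each had 1 SOX17FNV-only region, and Otx2 1 SOX2-only region. Otx2 lies on chromosome 14, where the pileup ratio was 1.29. Without SOX17FNV replicate 2, the SOX17FNV-only regions outnumbered the SOX2-only regions by 4 at Sox2, 3 at Esrrb, 1 at Tfcp2l1 and 2 at Otx2. With lists of equal length Nr5a2 had 1 more SOX17FNV-only than SOX2-only region, and the log2 odds of the general list were 0.10. With -log10 q of at least 5, the naive list turned to 4 SOX17FNV-only and 3 SOX2-only regions (log2 odds 0.25) and the formative and primed list to -0.17, with a difference of -2 at Dnmt3a and 1 at each of Esrrb and Tfcp2l1. With at least 10, the naive list had 2 and 1 (log2 odds 0.62), and the difference was 1 at Dppa2 and at Tbx3.

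Primitive and definitive endoderm genes had 5 SOX17FNV-only and 10 SOX2-only regions (log2 odds -0.64, -2.19 to 0.91, exact adjusted p = 0.638). Lamb1, which encodes a laminin chain of basement membrane, had 4 SOX2-only regions, Col4a1, a collagen gene, 1 SOX17FNV-only and 2 SOX2-only, Gata6, an endoderm transcription factor gene, 2 SOX17FNV-only, and Col4a2 1 SOX17FNV-only region. Trophectoderm genes had 8 and 4 (log2 odds 1.37, -0.37 to 3.10, exact adjusted p = 0.292). Elf5 and Tfap2c, both transcription factor genes of the trophoblast, each had 2 SOX17FNV-only regions, Tead4 had 1 of each direction and Eomes 1 SOX2-only region. Tead4 lies in the part of chromosome 6 with a pileup ratio of 0.844. Tfap2a was the list gene with an end called in both SOX2 libraries and no end called in either SOX17FNV library, and it was named after its values were seen. All 4 group-specific regions of primitive streak and mesoderm genes were SOX2-only, at Evx1, Fgf8, Tbx6 and Wnt3 (log2 odds with the added constant -2.81, -7.02 to 1.41, exact adjusted p = 0.292). Without SOX17FNV replicate 2 the direction turned at Col4a1 (by 2), Evx1 (by 1) and Wnt3 (by 1), and for the endoderm list to log2 odds of 0.13. Without SOX2 replicate 2 it turned at Col4a2 and Tfap2c (each -1) and Gata6 (-2). The trophectoderm list turned to 2 SOX17FNV-only and 4 SOX2-only regions with -log10 q of at least 5 (log2 odds -1.17) and to 0 and 1 with at least 10 (-1.97 with the added constant). The endoderm list turned to 2 and 0 with -log10 q of at least 10 (log2 odds with the added constant 1.95, with a difference of 1 at Col4a1) and to 6 and 5 with the top 50000 peaks of each list (0.39).

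Neuroectoderm genes had 5 SOX17FNV-only and 2 SOX2-only regions (log2 odds 1.69, -0.68 to 4.05, exact adjusted p = 0.432), with 2 SOX17FNV-only at Olig2 and 1 SOX2-only at each of Pax3 and Pax6. Endothelial and haematopoietic genes had 5 and 9 (log2 odds -0.48, -2.06 to 1.09, exact adjusted p = 0.656), with 2 and 3 at Pecam1, an endothelial adhesion molecule gene, none and 2 at Kdr, a VEGF receptor gene, none and 2 at Runx1, and 1 SOX17FNV-only at Cdh5. All 4 group-specific regions of germ line genes were SOX17FNV-only, 1 at each of Ddx4, Prdm1, Sycp3 and Tdrd1 (log2 odds with the added constant 3.53, -0.68 to 7.75, exact adjusted p = 0.281). The difference in counts of the germ line list stood at the percentile 98.5 of the random lists. The only two-cell-like gene with group-specific regions was Zfp352, with 2 SOX17FNV-only and 1 SOX2-only (log2 odds 1.36, -2.10 to 4.83, exact adjusted p = 0.656). Without SOX17FNV replicate 2 the direction turned at Runx1 (by 3) and for the neuroectoderm list (log2 odds -0.28) and the two-cell-like list (-0.54). Without SOX2 replicate 2 it turned at Cdh5 (-1) and Prdm1 (-4) and for the endothelial list (0.01). The neuroectoderm list turned with -log10 q of at least 10 (log2 odds -2.70), with lists of equal length (-0.32, with a difference of -1 at Olig2) and with the top 50000 peaks of each list (-0.29). With -log10 q of at least 5 and with the top 50000 peaks the difference was -1 at Sycp3, and with -log10 q of at least 10 no group-specific region of two-cell-like genes remained.

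Fibroblast genes, listed as markers of feeder cells, had 4 SOX17FNV-only and 3 SOX2-only regions (log2 odds 0.78, -1.38 to 2.94, exact adjusted p = 0.706). Col3a1, a fibrillar collagen gene, had 3 SOX17FNV-only regions, Postn 2 SOX2-only, Thy1 1 SOX17FNV-only and Fbn1 1 SOX2-only. Housekeeping genes, the control list, had 2 and 5 (log2 odds -0.96, -3.33 to 1.41, exact adjusted p = 0.638), with 3 SOX2-only at Ywhaz, 1 at Polr2a and 1 at Tbp, and 1 SOX17FNV-only at Actb. Without SOX17FNV replicate 2 the direction turned at Fbn1 (by 1). It turned for the fibroblast list without SOX2 replicate 1 (log2 odds -0.47) and for the housekeeping list without SOX17FNV replicate 1 (0.20) and without SOX2 replicate 2 (0.34). With the top 50000 peaks of each list the log2 odds were -0.88 for the fibroblast list, with a difference of -1 at Thy1, and 0.12 for the housekeeping list. With lists of equal length they were -0.49 for the fibroblast list, and with -log10 q of at least 10 they were 1.95 for the housekeeping list.

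**Figure D3:**
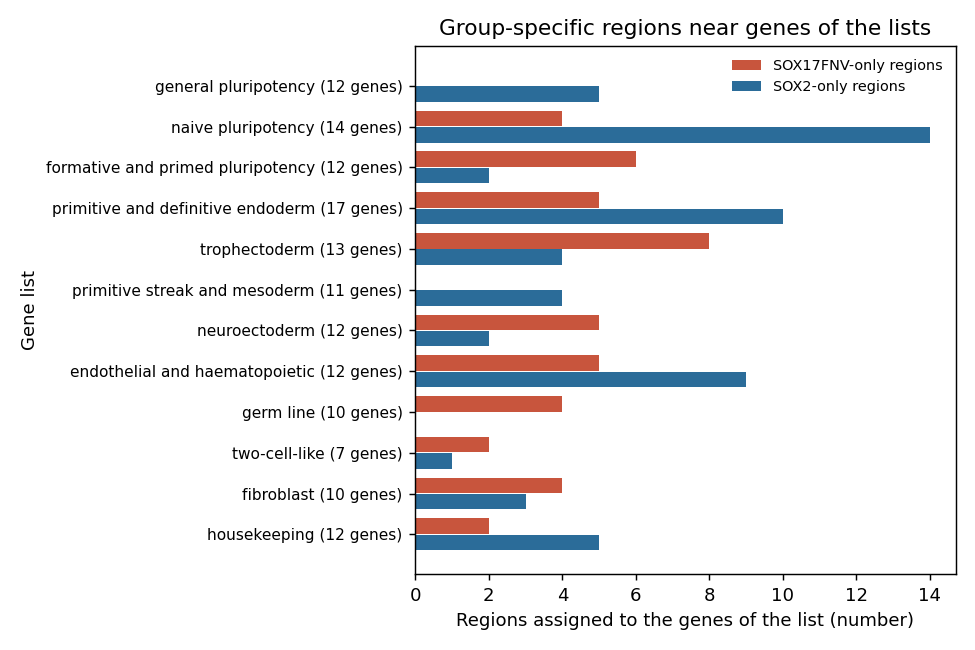
Number of SOX17FNV-only and SOX2-only regions (horizontal axis) assigned to the genes of each list (vertical axis, with the number of genes). No list passed the adjusted threshold, the smallest adjusted p being 0.281.

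Gene ends of the fixed lists were called in similar numbers in both groups. A gene was counted when a called region lay within 1 kb of either of its ends, which need not be the end with the promoter. In each library the ends of 13 of 14 naive genes, 11 of 12 formative and primed genes and at least 10 of 12 housekeeping genes were called. The ends of 12 or 13 of 17 endoderm genes and of 10 or more of 11 primitive streak genes were called too, and those of 0 of 7 two-cell-like genes. In all 4 libraries the ends of 8 of 13 trophectoderm, 10 of 12 neuroectoderm, 8 of 12 endothelial and 7 of 10 germ line genes were called. Of fibroblast genes, 8 and 6 of 10 were called in the SOX17FNV libraries and 8 and 6 in the SOX2 libraries.

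A smaller share of group-specific regions than of shared regions lay near gene ends. Shared regions were also wider, with a median of 834 bp against 384 bp for SOX17FNV-only and 423 bp for SOX2-only regions. A wider region is more likely to come within 1 kb of a gene end, and the shares were not adjusted for width. SOX17FNV-only regions were near a gene end in 5.11% (95% interval 4.53 to 5.74) and SOX2-only regions in 5.30% (4.79 to 5.86), against 25.9% (25.5 to 26.2) of regions shared by all libraries and 12.8% of all regions. These shares depended on the threshold, with 8.15% and 8.94% at -log10 q of at least 5 and 15.1% and 12.6% at 10 or more. No difference in this share passed the threshold (log2 odds -0.06, -0.29 to 0.18, adjusted p = 0.651, Fisher's exact test). The sign of this value turned without SOX2 replicate 1 (log2 odds 0.29, Fisher's exact p = 6.07e-06) and without SOX2 replicate 2 (0.07), and the value passed the threshold as -0.42 without SOX17FNV replicate 1 and -0.15 without SOX17FNV replicate 2. Nearly equal parts lay inside genes, 49.5% and 48.8%. Fewer SOX17FNV-only regions (16.3%, 15.3 to 17.4) than SOX2-only regions (19.5%, 18.6 to 20.5) lay more than 50 kb from any protein-coding gene (log2 odds -0.31, -0.45 to -0.18, adjusted p = 8.81e-06, Fisher's exact test). This difference was -0.04 without SOX17FNV replicate 1, and the split by replicate number gave a log2 odds of -0.28 for the same share. With lists of equal length, the split by factor gave -0.44 and the split by replicate number 0.51.

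Chromosome 14 stood apart. Of its 8978 regions, 777 (8.65%) were SOX17FNV-only, against 2.75% on the other chromosomes (odds ratio 3.35, 3.10 to 3.63, adjusted p = 1.00e-151, Fisher's exact test), and 1.57% were SOX2-only, against 4.23% (odds ratio 0.361, 0.305 to 0.427). The chromosome held 14.9% of all SOX17FNV-only regions and 2.02% of all SOX2-only regions. In the split by replicate number, 3.83% and 4.37% of the specific regions lay there. Chromosome X was opposite, with 7.56% SOX2-only regions against 4.01% elsewhere (log2 odds 0.97, 0.80 to 1.14, adjusted p = 6.50e-23, Fisher's exact test) and 1.75% SOX17FNV-only (odds ratio 0.558, 0.439 to 0.707). Chromosome 6 had 5.39% SOX2-only regions (odds ratio 1.36, 1.24 to 1.49, adjusted p = 1.57e-09, Fisher's exact test). By the same exact test, SOX2-only shares on chromosomes 1 (odds ratio 1.22, adjusted p = 0.000116), 12 (1.18, 0.0236), 13 (1.16, 0.0296) and 17 (0.806, 0.00561) also passed the threshold. So did SOX17FNV-only shares on chromosomes 2 (0.828, exact adjusted p = 0.00561), 3 (0.813, 0.0144) and 6 (0.842, 0.0278). The other chromosomes in these tests include chromosome 14. The SOX17FNV-only share of the autosomes without chromosome 14 was 2.77%, against 2.58%, 2.53% and 2.61% on chromosomes 2, 3 and 6. No test was run against that share. On chromosome X from 5 to 45 Mb, 13.9% of regions were SOX2-only and 0.653% SOX17FNV-only, and on chromosome 6 from 120 to 150 Mb 7.13% and 1.19%. With lists of equal length the odds ratio of SOX17FNV-only regions on chromosome 14 was 3.12 (2.88 to 3.38), and without SOX2 replicate 1 their log2 odds were 0.98, against 1.74 with all libraries.

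**Figure D4:**
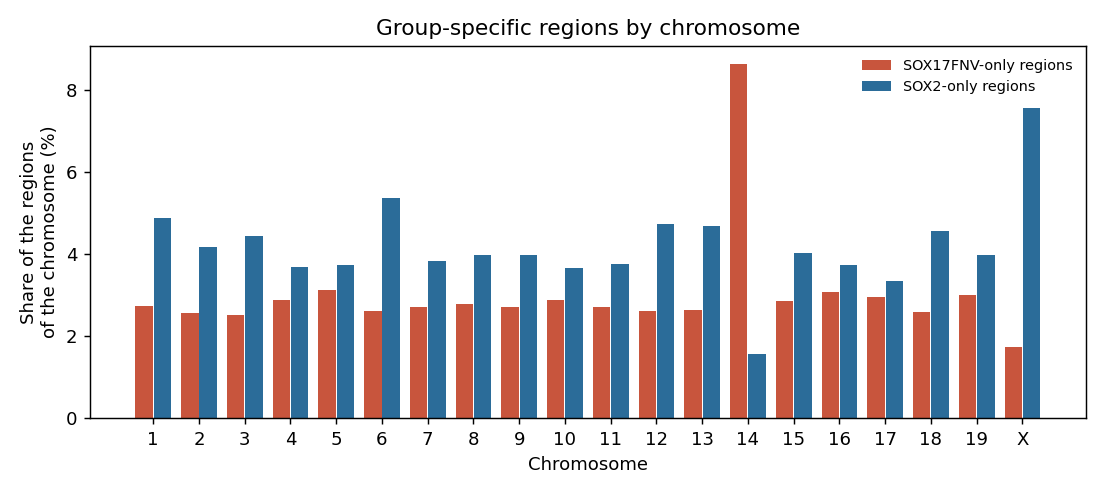
Share of the regions of each chromosome, in percent (vertical axis), that were SOX17FNV-only or SOX2-only, for chromosomes 1 to 19 and X (horizontal axis). Chromosome 14 has 8.65% SOX17FNV-only and 1.57% SOX2-only regions, and chromosome X 1.75% and 7.56%.

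**Figure D5:**
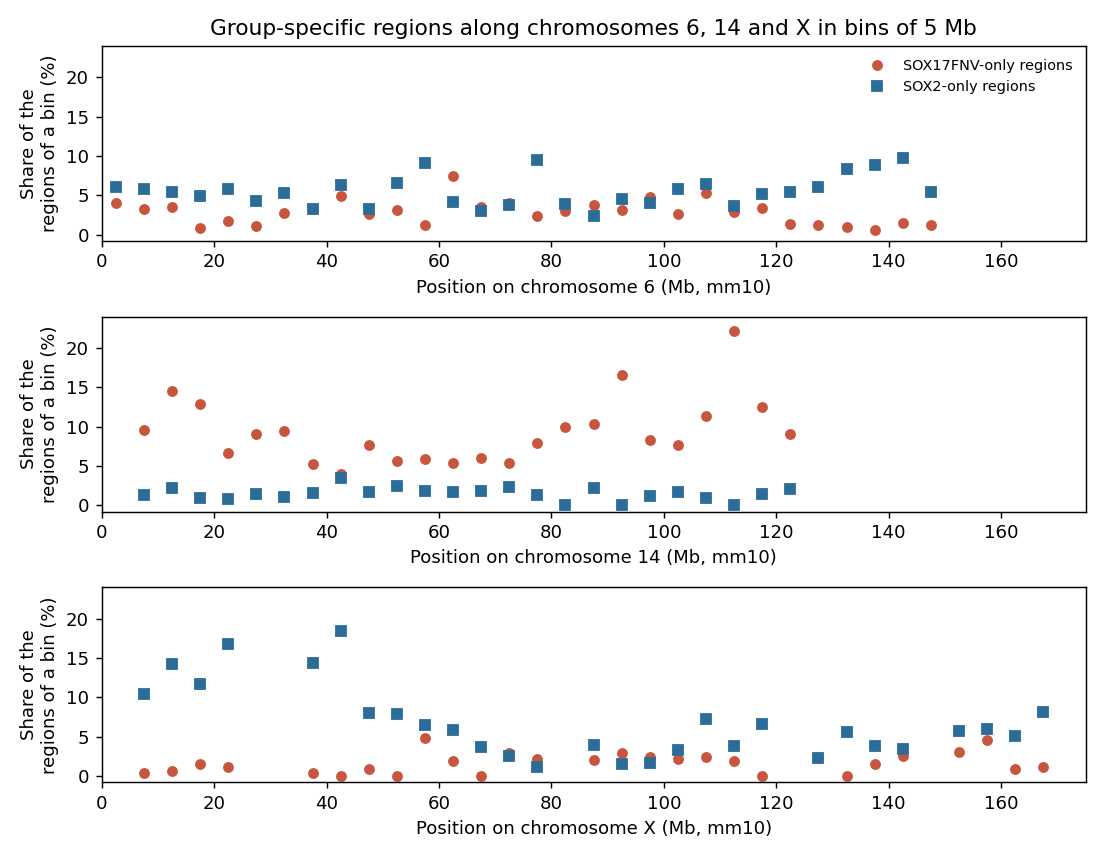
Share of regions, in percent (vertical axis), that were SOX17FNV-only or SOX2-only in bins of 5 Mb along chromosomes 6, 14 and X (horizontal axis, Mb in mm10); bins with at least 20 regions are drawn. SOX17FNV-only shares lie above SOX2-only shares along chromosome 14, and SOX2-only shares are high from 5 to 45 Mb on chromosome X and from 120 to 150 Mb on chromosome 6.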

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

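For the patterns below, the tests of stretches on other chromosomes and of reads from the lentiviral genes were chosen only after the result was seen.

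Chromosome 14 stood out in a signal the comparisons do not use, the summit pileup of regions called in all libraries. Relative to the other autosomes it was 1.12 and 1.17 in the SOX17FNV libraries and 0.886 and 0.893 in the SOX2 libraries, a ratio of 1.29, against 0.915 to 1.05 on the other autosomes. More copies of the chromosome in the SOX17FNV cells could account for it, and 84% of its bins of 5 Mb had a ratio above 1.1, but no copy number was measured and an effect of the factor along whole chromosomes was not tested. Unequal list length and the opening of a few loci were excluded as the whole cause, since the odds ratio was 3.12 with lists of equal length and 96% of the bins had a SOX17FNV-only share above that of the other autosomes. On chromosome 6 from 120 to 150 Mb and chromosome X from 5 to 45 Mb, found in replicate 1, 100% of the bins kept their sign in replicate 2, with ratios of 0.819 and 0.723 there (0.862 and 0.742 in replicate 1), and the search begun in replicate 2 also found chromosome 15 from 15 to 35 Mb (0.863, and 0.874 in replicate 1).

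The split of the libraries by replicate number gave as many specific regions as the split by factor, 12967 against 12222. Of the 12967, 11824 were called in the replicate 1 libraries alone. Unequal list length may account for part of the 12967, since with lists of equal length the factor gave 1.52 times as many as the number. With -log10 q of at least 10 the number gave more than the factor (log2 ratio of factor to number -1.09). With lists of equal length the number still gave 1.79 times as many as the crossed split. Of these regions, 5031 were called in the replicate 1 libraries alone and 2670 in the replicate 2 libraries alone. A batch shared by libraries of the same number may account for another part. The ratio cannot tell a batch from any other difference between the replicate 1 and replicate 2 libraries, since each crossed pair holds 1 of each. The labels give no batch, though libraries of the same number share a mark in the deposited peak names that the labels do not explain, and with 3 splits no share of splits below 0.333 can be reached, so an effect of the factor on the total count was not shown.

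Inside Sox2 a region was called in the SOX2 libraries alone, and the relative pileup over Sox17 was 1.78 times as high in the SOX17FNV libraries. Reads from the lentiviral cDNA, mapped to the gene it was made from, could give both, and so could open chromatin at these genes. The exon borders and the species of the cDNA are not given in the sources used here, so these explanations cannot be told apart.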

How the results depend on the processing

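Leaving out chromosome 14, leaving out chromosomes 6, 14 and X, and every alternative for the chromosomes other than lists of equal length were tests chosen only after the result was seen.

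The odds of SOX17FNV-only regions on chromosome 14 kept their direction and their side of the threshold in all 10 alternatives (log2 odds 0.98 to 1.91), as did those of SOX2-only regions (-1.54 to -0.89). No gene list passed under any alternative but the replicate block. Of 54 named genes, 11 kept their direction with -log10 q of at least 10, 20 with at least 5, 23 with the top 50000 peaks per list, 39 with equal list length, 45 with 50% coverage and 52 with summit windows. With 1 library left out, 37 to 50 kept it. Where a value changed below, the cause was not tested, except that stricter lists hold fewer peaks and a left-out library leaves 1 library to define its group. With -log10 q of at least 10, there were 1455 SOX17FNV-only, 1222 SOX2-only and 13927 regions called in every library. The log2 ratio of the factor split to the number split was -1.09, the Jaccard difference -0.0126 and the log2 odds of lying near a gene end 0.30. List log2 odds were 0.62 for naive pluripotency, 1.95 for endoderm and housekeeping, -1.97 for trophectoderm, and -2.70 for neuroectoderm, while the two-cell-like and fibroblast lists held no group-specific region and gave no value. The endoderm and trophectoderm values include the constant added where a list had no region of a group. The difference in regions was 1 at Cobl, Col4a1, Dppa2 and Tbx3. With -log10 q of at least 5, there were 2834 SOX17FNV-only, 2696 SOX2-only and 28699 regions called in every library, with a log2 ratio of -0.76 and a Jaccard difference of -0.000421. List log2 odds were 0.25 for naive, -0.17 for formative and primed pluripotency, and -1.17 for trophectoderm. The difference was -1 at Sycp3, -2 at Dnmt3a, and 1 at Esrrb and Tfcp2l1. With equal list length, the log2 ratio was 0.60, the Jaccard difference 0.0249 and the gene-end log2 odds 0.040. List log2 odds were 0.10 for general pluripotency, -0.32 for neuroectoderm and -0.49 for fibroblast. The difference was 1 at Nr5a2 and -1 at Olig2. With the top 50000 peaks per list, there were 3273 SOX17FNV-only, 3804 SOX2-only and 29865 regions called in every library, with a log2 ratio of 0.82 and a Jaccard difference of 0.0366. List log2 odds were 0.39 for endoderm, -0.29 for neuroectoderm, -0.88 for fibroblast and 0.12 for housekeeping. The difference was -1 at Sycp3 and Thy1, 1 at Cobl and 2 at Tfcp2l1. With 50% coverage of the region, 35901 regions were called in every library, the gene-end log2 odds were -0.29 and the difference at Dppa2 was 1. With summit windows of 250 bp either side, the Jaccard difference was 0.0172 and the housekeeping log2 odds 0.39. With a gene end within 2.5 kb, the gene-end log2 odds were 0.083, without chromosome 14 0.012, and without chromosomes 6, 14 and X 0.088. With the nearest gene within 10 kb, the fibroblast log2 odds were -0.20.

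Without 1 library in turn (leave-one-out), SOX17FNV-only regions ranged from 7470 to 25111 and SOX2-only regions from 9022 to 28780. The log2 odds of lying near a gene end ranged from -0.42 to 0.29 and of lying over 50 kb from a gene from -0.39 to -0.041. List log2 odds ranged from -0.54 to 0.0052 for endothelial, -0.47 to 0.75 for fibroblast, -0.41 to 0.34 for housekeeping, -0.28 to 1.16 for neuroectoderm, -0.68 to 0.13 for endoderm and -0.54 to 2.92 for two-cell-like genes. The difference in regions ranged from -1 to 1 at Cdh5 and Evx1, -4 to 2 at Col4a1 and Prdm1, -1 to 7 at Col4a2, -7 to 3 at Esrrb and Runx1, -5 to 1 at Fbn1, -2 to 3 at Gata6, -3 to 2 at Otx2, -4 to 4 at Sox2, -1 to 4 at Tfap2c, -4 to 1 at Tfcp2l1 and -2 to 1 at Wnt3.

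In the replicate block, which compares libraries of the same number although the labels do not say what the numbers mark, 1 of the gene lists passed. This was naive pluripotency, with counts of 62 for SOX17FNV and 110 for SOX2 summed over the 2 numbers (log2 odds -0.68, adjusted p = 0.0345 by the Mantel-Haenszel test and 0.0340 by an exact conditional test added after seeing the data, both over regions, with adjusted p from 0.0345 to 1 over 15 alternatives). The list's 4 SOX17FNV-only and 14 SOX2-only regions were counted under both numbers. Both tests treat the numbers as independent, so these p-values overstate the evidence. The housekeeping log2 odds turned to 0.15. Over regions, the call differences of replicate 1 minus replicate 2 correlated between the groups by 0.0619 (0.0745 with lists of equal length and 0.0854 with the top 50000 peaks). The motif alternatives were not run, since no genome was used, nor was 50% coverage for the Jaccard index, which does not use region calls. The block leaves the region counts as they are by construction, and in place of leaving out a library each within-group pair was given alone. The lowest called pileup, 10 to 13, was higher where the background was higher, and whether depth limits the calls was not tested. The list test called 26% of simulated lists with an odds ratio of 16. With the nearest gene within 10 kb, or the gene body and 5 kb around it, the two-cell-like list held no group-specific region and gave no value.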

Other observations

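Outside chromosome 14 and the stretches of chromosomes 6 and X, which were chosen only after the result was seen, 157677 regions remained, of which 4407 (2.79%) were SOX17FNV-only and 6467 (4.10%) SOX2-only. A stretch of chromosome 15 from 15 to 35 Mb, found only when the search began in replicate 2, was not removed from this count. For the share of regions more than 50 kb from a gene, with lists of equal length, the split by factor gave a log2 odds of -0.44, the split by replicate number 0.51 and the crossed split -0.01.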
